A study of Gallus gallus with 300 samples.

How the data were processed

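The data are single cells of the sensory epithelium of chicken utricles at posthatch day 7. Per the labels' protocols, the otolithic membranes were taken off, epithelia were freed from the stroma with thermolysin, several epithelia were pooled per experiment and dissociated, and viable single cells were sorted into well plates. The protocols describe independent sort batches, and no label ties a batch to a plate or an animal to a cell. Libraries were made by a full-length method with oligo-dT priming, PCR amplification and no molecular identifiers, per the labels' protocols. Each of the 300 cells has its own file of 13643 gene rows, and its deposited values are expected counts per gene, estimated counts that need not be whole. STAR, RSEM and FastQC are named in the submitters' processing notes, and the genome build, the annotation and the versions are not given in the sources used here.

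The 12 symbols found on 2 rows were summed, which left 13631 gene symbols, used as the files give them. Expected counts were not rounded, because no count model was fitted, except for sums of counts and thinning, where whole numbers are needed. A cell was kept with at least 1000 genes of 1 count or more and a total of at least 50000 counts, which left 276 cells. Counts were divided by the cell's total and multiplied by 1000000 to give CPM. A gene was measured when it reached 10 CPM in at least 5 cells, as 10677 did. No doublet caller was run, since cells were sorted singly into wells, and wells with 2 cells were weighed only for cells of intermediate marker score.

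The design, the gene lists, the markers and the rule for named genes were set before the data were examined. Genes were split into a pair of sets, A and B, by a hash of their name, and the 497 genes of any gene list or marker list were left out of clustering. From the 6527 remaining genes of set A, the 1000 most variable were centred, scaled with a cap at 10 and reduced to 20 principal components, and Ward clustering gave 8 clusters. The set A genes that define the clusters are not reported as results. A cluster was named for the marker list with the largest share of members at 10 CPM or more in at least 50% of its cells, and at least 3 such members were needed. The developing, type I, type II, striolar and extrastriolar lists were not used for this name. A hair cell-like cluster with at least 3 such members of the developing list was also called developing. Hair cell-like and supporting cell-like cells were clustered again within their class with 10 components and 3 sub-clusters, named in the same way when the list was also highest in that sub-cluster. Type I, type II, developing, striolar and extrastriolar markers served for hair cell-like cells, and striolar and extrastriolar markers for supporting cell-like cells. The marker score was the mean z value of the hair cell markers minus that of the supporting cell markers, scaled so that the median supporting cell-like cell was at 0 and the median hair cell-like cell at 1.

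For each gene, CPM were averaged over cells within a plate and then over the plates with at least 5 cells of both sides, and the log2 ratio was taken with a pseudocount of 1 CPM, which understates the ratio of low genes. Where fewer plates had 5 cells, all cells were averaged. The 5597 measured genes of set B or of a list were read out. Named genes were the 12 with the highest and the 12 with the lowest log2 ratio (6 and 6 for sub-clusters) that reached 10 CPM in at least 50% of the cells of the higher side (30% for sub-clusters) and went the same way on every plate used. From each list 2 to 4 members with the largest ratio, and members that went the other way, were named beside them. A list was described by the median log2 ratio of its measured members and its percentile among 10000 random lists of the same size matched on mean expression. The lists cover mechanotransduction, hair bundle, ribbon synapse, channels and receptors, calcium buffering, Notch, Wnt, FGF and BMP, retinoic acid, gap junction and ion transport, otolithic membrane and matrix, epithelial adhesion and progenitor factors, cell cycle, immediate early and stress genes, apoptosis, ribosomal proteins and nuclear oxidative phosphorylation. Marker lists cover hair, supporting, developing, type I, type II, striolar, extrastriolar, stromal, endothelial, immune, glial, melanocyte, neuron and dark cells. Erythroid markers and mitochondrially encoded genes had 0 members under their listed symbols and were not analysed here. Some genes are in more than 1 list, such as OCM and SOX10.

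The labels give 1 group and name no animal or batch for a cell, so no replicates could be compared. No test between cell groups was run and no p-value computed, and the percentiles describe these cells only. Plates were compared by Dixon's ratio with its critical value for 5 values. Shares have exact binomial intervals and summed counts exact Poisson intervals, both at 95%. A share of 0 is given with the share that 3 counts would make, which limits cells with reads of the gene and not cells that express it. Class totals rest on 182 and 94 cells with median totals far above the 50000 counts of the filter. The Poisson error of their read counts is therefore small beside the spread between cells. Without molecular identifiers, the error of counting molecules cannot be read from them. Near-identical gene copies can share reads under the authors' estimated counts, which was not tested here.

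The ratio and list steps were tested on simulated counts for the comparison of hair cell-like with supporting cell-like cells, over 10677 genes of which 200 were changed, 50 at each of 4 sizes. Genes changed 2-fold had a median log2 ratio of 1.03 (noise-free value 0.96), and 46 of 50 had the right direction. For 4-fold the median was 1.69 (1.94) with 48 of 50, for 8-fold 3.04 (2.93) with 50 of 50 and for 16-fold 3.90 (3.94) with 50 of 50. The 10477 unchanged genes had a median of 0.23 (noise-free 0.19, a shift from scaling to the total), and 1071 of them went the same way on all 5 plates. A list of 12 genes changed 2-fold reached percentile 100 and one of 12 unchanged genes 12.5. Ward clustering into 2 clusters put 89.1% of 276 simulated cells in their class.

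Alternatives changed the cell filter, the clustering genes, the number and method of clusters, the number of components, the scaling, the pseudocount, the averaging, the filter on low genes, the number of sub-clusters, the detection limit, the score bounds and the plates, each 1 at a time. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.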

Results

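Single cells from the sensory epithelium of the chicken utricle, a vestibular organ of the inner ear, were profiled by full-length single-cell RNA sequencing. The animals were wild type and at posthatch day 7. The data comprise 300 sorted cells on 5 well plates, with 53, 53, 66, 68 and 60 cells on plates 2 to 6. Deposited totals ran from 62846 to 1234012 counts per cell, with a median of 395671, and the median cell had 2739.5 genes with at least 1 count. The filter on genes and counts removed 24 of the 300 cells, and the median of the others was 406690.5 counts and 2862 genes. All cells came from 1 kind of tissue, and the labels name no animal for a cell, so every comparison is between groups of cells of 1 tissue. Differences between cell groups were not tested, and no difference was set against the spread between animals. Values below are mean counts per 1000000 (CPM) ± SD over the plate means (n = 5 plates unless stated), and the SD is that of plates, whose animals and sort batches the labels do not name. Binomial 95% intervals cover only the error from the number of cells, and neither they nor the Poisson intervals cover the spread between animals. Poisson 95% intervals treat reads as independent. Reads amplified without molecular identifiers are not independent molecules, so the Poisson intervals are too narrow.

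The title of the series names cell type identity as its subject, and the cells fell into hair cells, the mechanosensory cells, and supporting cells, the non-sensory cells around them. Hair cell-like clusters held 65.9% (60.02 to 71.5%, exact binomial interval) of the cells kept, with 33, 38, 32, 41 and 38 cells on plates 2 to 6. Supporting cell-like clusters held 94 cells, 34.1% (28.5 to 39.98%). Across plates the hair cell-like share averaged 66.5% ± 8.90 (SD, n = 5 plates), from 32 of 61 cells on plate 4 to 38 of 50 on plate 3. A cluster of 13 of the hair cell-like cells, 4.71% of all cells (2.53 to 7.92%), also carried 3 detected markers of developing hair cells and contained cells from all 5 plates. Its size depended on the clustering, with 0 developing cells without plate 4 and 13 to 32 under the other settings. No cluster was named for stromal, endothelial, immune, glial, neuronal, melanocyte or dark cells, and no cell was left without a class. The stromal and melanocyte lists had 1 measured member each and the endothelial, immune and dark cell lists 2 each. Since a name needs 3 detected members, these names were out of reach except in very small clusters. Absence of these cell types is therefore not shown. Under 5 other settings a glial cell-like cluster of 1 to 4 cells was named, which each time included at least 1 cell of supporting cell-like sub-cluster 3. Clusters 1, 2 and 5 were hair cell-like with 9, 8 and 10 of 12 markers detected, and cluster 6 was the developing one with 10. Supporting cell-like clusters 3, 4, 7 and 8 had 8, 10, 5 and 8 of 13 markers detected, and clusters 7 and 8 held 6 and 2 cells. Under a stricter cell filter, the hair cell-like share was 79.1%. Cells had been sorted for viability and filtered on gene number, which can set these shares.

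**Figure D1:**
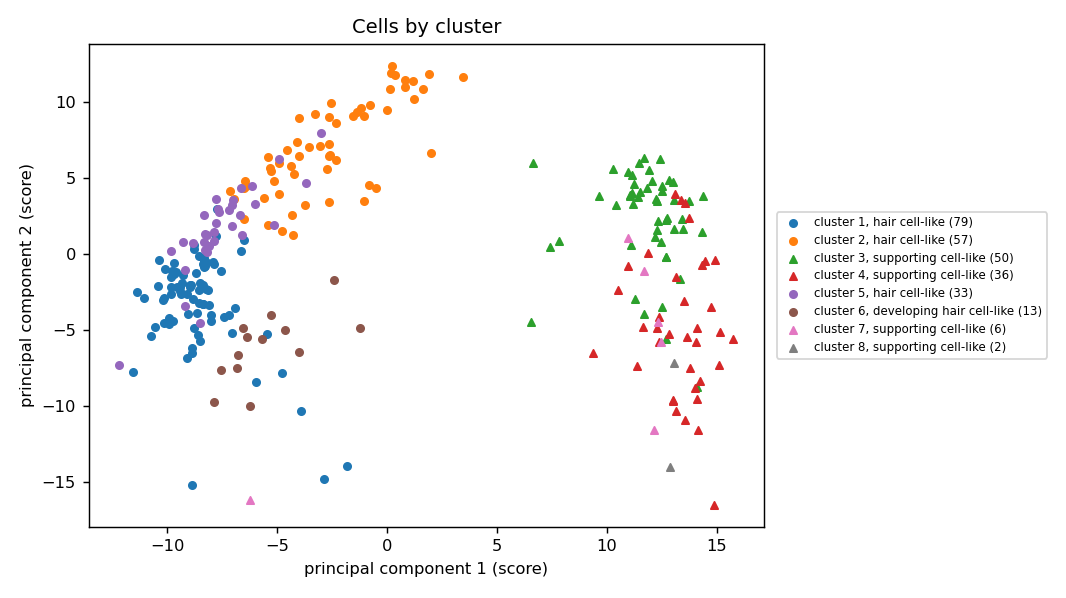
Scores of the cells kept on principal components 1 and 2 (no unit), 1 point per cell, coloured by cluster, with circles for hair cell-like and triangles for supporting cell-like clusters and the number of cells in brackets. The hair cell-like cells lie mostly at low and the 94 supporting cell-like cells mostly at high scores of component 1, and 1 cell of cluster 7 lies among the hair cell-like cells.

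Hair cell-like and supporting cell-like cells also differed in depth. The median hair cell-like cell had 3458 genes and the median supporting cell-like cell 1823.5. After each cell was thinned to 50000 counts the medians were 2910 and 1630.5 genes, and no cell was too shallow for this.

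The comparison of hair cell-like with supporting cell-like cells asked which genes separate these cell types among genes that the clustering did not use. OCM, which encodes the calcium-binding protein oncomodulin, had 9671 ± 1360 CPM in hair cell-like and 38.8 ± 17.2 CPM in supporting cell-like cells, a log2 ratio of 7.92. It reached 10 CPM in 90.1% of hair cell-like and 22.3% of supporting cell-like cells, and its summed counts were 816181 (814411 to 817954, exact Poisson interval) and 1250 (1182 to 1321). CHRNA10, a subunit of the nicotinic receptor at efferent synapses on hair cells, had 381 ± 29.8 CPM in hair cell-like cells and 0 counts in the 94 supporting cell-like cells, which allows reads of it in up to 3.19% of cells. The same was seen for BAIAP2L2, a protein of stereocilia tips, with 218.4 ± 35.6 CPM, and for GRIA2, an AMPA-type glutamate receptor subunit, with 164.2 ± 120.5 CPM. ADGRV1, a receptor of the links between stereocilia, had 462 ± 270 against 1.87 ± 3.28 CPM.

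Other genes higher in hair cell-like cells were the deafness-linked protease gene TMPRSS3 (779 ± 127.2 against 4.42 ± 9.64 CPM) and CHGA, which encodes the granule protein chromogranin A (817 ± 144.3 against 4.83 ± 10.8 CPM). GRTP1 had 425 ± 33.6 against 2.51 ± 5.60 CPM, and LRTOMT, a gene linked to deafness, 952 ± 135.6 against 8.16 ± 12.3 CPM. SYT14 of the synaptotagmin family (649 ± 137.3 against 5.85 ± 12.8 CPM), CLIC5 of the stereocilia base (948 ± 165.1 against 9.33 ± 18.3 CPM) and DFNB59, which encodes pejvakin (439 ± 76.3 against 4.17 ± 9.22 CPM), completed the group. The 9 of these 12 genes with counts in both classes had log2 ratios of 6.41 to 7.92. The rule for named genes required all 12 to be higher on each of the 5 plates.

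Another 12 genes were higher in supporting cell-like cells. Among them OTOGL, GJB2 and SLC1A3 are supporting cell markers that served to name the class, so their direction is not an independent result. OTOGL, an otogelin-like protein of acellular membranes, had 865 ± 152.97 CPM in supporting cell-like and 2.23 ± 1.87 CPM in hair cell-like cells, a log2 ratio of -8.07. The gap junction gene GJB2 had 3554 ± 406 against 26.9 ± 19.6 CPM, and the glutamate transporter gene SLC1A3 2384 ± 619 against 23.8 ± 19.9 CPM. JAG1, a Notch ligand, had 946 ± 274.8 against 6.502 ± 9.87 CPM. OTOP1, a proton channel required for otoconia, had 1458 ± 429 against 9.67 ± 7.96 CPM. The matrix genes MATN4 and SPARC had 6127 ± 2687 and 4410 ± 1837 CPM in supporting cell-like cells, against 51.04 ± 31.7 and 45.2 ± 29.2 CPM. Also higher in supporting cell-like cells were HEG1 (305 ± 59.9 CPM, log2 ratio -8.17), CDO1, a cysteine dioxygenase (1221 ± 183.9 CPM, -7.30), and the transcription factor gene SOX10 (332 ± 210 CPM, -7.27). GGT1, a gamma-glutamyltransferase (549 ± 110 CPM, -7.08), and the hypoxia-inducible factor gene EPAS1 (277.1 ± 148.7 CPM, -6.62) were the others. The same rule required all 12 to be lower in hair cell-like cells on each of the 5 plates.

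Gene lists for the sensory apparatus were higher in hair cell-like cells. Each list is given by the median log2 ratio of its members ± SD of the 5 plate medians, and by the percentile of that median among 10000 random lists matched on expression. All 12 measured members of the mechanotransduction list were higher (median 5.11 ± 0.917, percentile 100), among them the channel gene TMC2 (234.3 ± 128.03 CPM against 0 counts), CLRN2 (log2 ratio 6.15), TMIE (5.84) and the tip link cadherin gene CDH23 (5.76). Of 22 hair bundle genes 17 were higher (median 3.85 ± 1.34, percentile 100), led besides BAIAP2L2 and ADGRV1 by the myosin gene MYO3A (log2 ratio 6.88) and the actin-bundling gene FSCN2 (6.33), while FSCN1 (-2.88) and the radixin gene RDX (-0.81) were lower on every plate. Of 20 ribbon synapse genes 19 were higher (median 3.18 ± 1.29, percentile 100), including RIMS2 (126.3 ± 50.3 CPM against 0 counts), the glutamate transporter gene SLC17A6 (5.48), ERC2 (5.26) and the calcium channel gene CACNA1D (5.07), with UNC13B (-2.67) lower. All 11 measured channel and receptor genes were higher (median 4.06 ± 1.28, percentile 100), such as the potassium channel gene KCNA10 (513 ± 87.4 CPM against 0 counts), the sodium channel gene SCN8A (5.38) and CHRNA9 (4.57). Calcium buffering genes had a median of 2.28 ± 1.23 (percentile 99.93) with 10 of 13 higher, such as CABP1 (5.69) and the calretinin gene CALB2 (2682 ± 444 against 59.9 ± 70.1 CPM), and with S100A6 (-4.62) and S100A1 (-2.49) lower. Of 69 nuclear genes of oxidative phosphorylation, 68 were higher (median 1.17 ± 0.149, percentile 100), among them COX6C (2.65), NDUFS6 (2.00) and COX8A (1.95), and ATP5G2 (-0.46) was lower.

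Signalling and matrix lists were lower in hair cell-like cells. In the Notch list, 4 of 16 members were higher and the median was -2.81 ± 0.530 (percentile 0). The Notch target genes HEYL (5.47 ± 11.1 against 509 ± 139.04 CPM) and HES5 (64.6 ± 36.2 against 4480 ± 1507 CPM) and the receptor gene NOTCH1 (log2 ratio -6.04) were lower, while the ligand genes DLL4 (15.6 ± 7.62 CPM against 0 counts) and JAG2 (3.01) were higher. Otolithic membrane and extracellular matrix genes had a median of -5.04 ± 0.424 (percentile 0), with LAMB1 at 0 counts against 90.1 ± 116.3 CPM, and 1 of 20 members, TNC (0.17), was not lower. The single-plate medians of this list were smaller in size, -4.28 to -3.39, and its median was -1.27 as the difference of mean log2(CPM + 1). OC90, an otoconial protein gene, had the largest ratio of this list (-8.70), and it was lower on only 2 of the plates. Wnt pathway genes had a median of -2.03 ± 1.17 (percentile 0), with DKK3 (35.5 ± 22.5 against 2865 ± 1150 CPM), SFRP2 (0 counts against 70.5 ± 45.5 CPM), WNT7A (-5.31) and SFRP1 (-5.23) lower and RSPO3 (4.03) and LGR6 (2.71) higher. Genes of the FGF and BMP pathways had a median of -1.23 ± 0.766 (percentile 0.13), with the receptor gene FGFR1 (-4.60) and the feedback inhibitor genes SPRY1 (-4.19) and SPRY2 (-4.15) lower, and BMP2 (501 ± 120 against 25.6 ± 36.7 CPM), FGFR2 (2.36) and SMAD7 (1.58) higher. For epithelial adhesion and progenitor factors the median was -1.40 ± 0.319 (percentile 0.01), with SOX9 (-5.07), EPCAM (160 ± 40.95 against 2608 ± 753 CPM) and CDH1 (0 counts against 13.98 ± 9.12 CPM) lower and LMO4 (1.60) and PAX2 (1.11) higher. The plate medians of these factors were all smaller in size, -1.09 to -0.39. Immediate early and stress genes had a median of -2.23 ± 1.24 (percentile 0), with EGR1 (225.4 ± 118.8 against 3768 ± 1730 CPM) and GADD45B (-4.42) lower and SOD1 (1.58) and the heat shock gene HSPA2 (1.50) higher. On plate 6 the median of the stress list was 0.42, and EGR3 (-3.81) had the opposite sign without plate 3 (1.25) or plate 5 (0.14).

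In several lists the members went both ways. Genes of gap junctions and ion transport had a median of -1.54 ± 0.885 (percentile 0.07) with 6 of 13 members higher. The gap junction genes GJB6 (275.5 ± 92.8 against 23265 ± 2845 CPM) and GJA1 (-5.40) were lower, and the potassium channel gene KCNK1 (3.31) and the sodium pump gene ATP1B1 (1032 ± 64.6 against 120 ± 111.8 CPM) were higher. This median was 0.12 when clustering genes from both gene sets were used, 0.14 with 12 clusters and 0.15 without the cells between the marker score bounds, and -4.11 to -1.67 with 1 plate left out, and its plate medians ran from -1.88 to 0.24. Retinoic acid genes had a median of 0.23 ± 0.999 (percentile 51.2) and a mean of -0.15. The retinoic acid-binding protein gene CRABP1 was higher (1366 ± 316 against 17.9 ± 23.9 CPM), and the synthesis gene ALDH1A3 (17.2 ± 16.7 against 808 ± 436 CPM) and STRA6 (-6.20) were lower. Cell cycle genes had a median of -0.54 ± 1.14 (percentile 16.1), with TYMS (-4.25) and the cyclin gene CCND1 (-4.22) lower on every plate. Apoptosis genes had a median of -0.17 (percentile 25.04), although their plate medians were all positive, 0.098 to 0.757, and MCL1 (-1.81) was lower on every plate. Ribosomal protein genes had a median of -0.33 ± 0.129 (percentile 0.05) with 17 of 71 members higher, which was 0.0048 as the difference of mean log2(CPM + 1). RPS23 (-1.41) and RPS3 (-1.39) were lower and RPL22L1 (2.88) and RPS27L (1.83) higher.

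**Figure D2:**
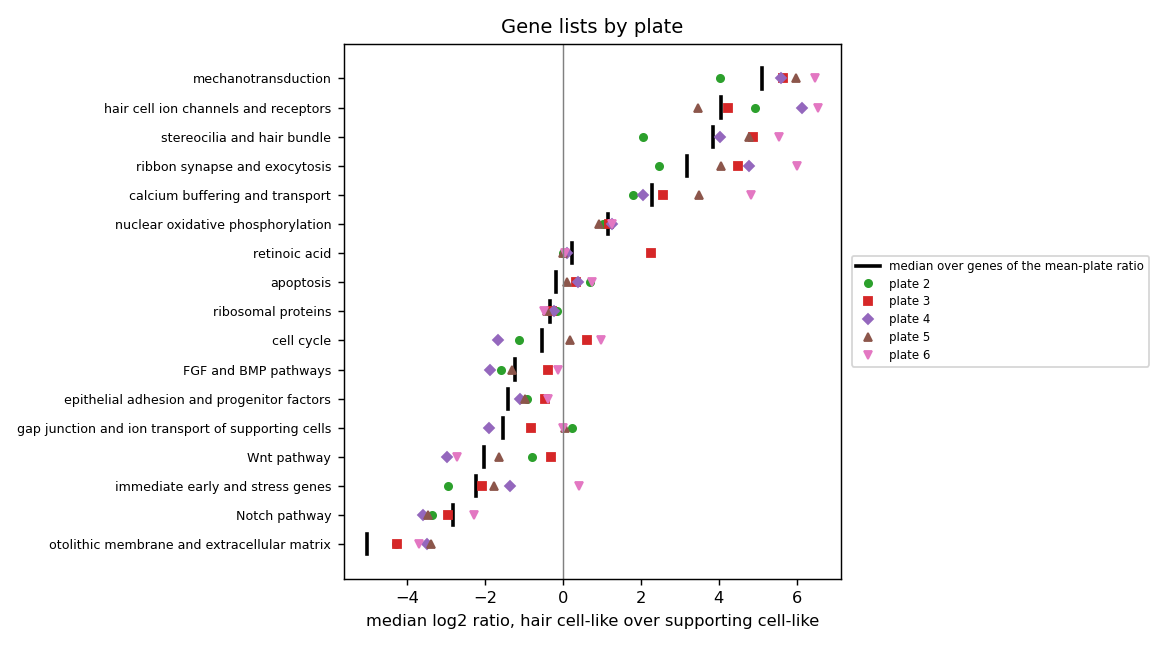
Median log2 ratio of hair cell-like over supporting cell-like cells on the horizontal axis for each gene list on the vertical axis, with 1 symbol per plate and a black bar for the median of the ratios of mean plate values. The mechanotransduction list lies between 4.02 and 6.47 on all 5 plates, the Notch list between -3.58 and -2.28, and the retinoic acid list at 2.27 on plate 3 against 0 to 0.097 on the others. The ribosomal protein medians, below 0 here, have a value of 0.0048 as the difference of mean log2(CPM + 1).

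Marker lists that gave names to the classes are not independent results, and their medians were 5.42 ± 1.43 for hair cell and -6.24 ± 0.543 for supporting cell markers. The same holds for naming markers that also belong to other lists, such as CALB2, HES5, GJB6, OTOGL and TECTA. Type I hair cell markers had a median of 4.49 ± 0.908 (percentile 99.98), type II markers 1.84 ± 0.363 (percentile 95.7) and developing hair cell markers 0.89 ± 0.815 (percentile 87.8). Markers of the striola, the central stripe of the utricle, had a median of -1.40 ± 1.82 (percentile 4.96) and a mean of 0.47, and extrastriolar markers a median of 1.18 ± 1.58 (percentile 83.5) and a mean of -0.13. Glial markers were lower in hair cell-like cells (median -4.73 ± 2.77, percentile 0.14, 3 members), with MBP at 10.1 ± 8.00 against 293.7 ± 537 CPM. Their member PMP22 was lower in mean (-1.16) but higher on 4 of the 5 plates, and reached 10 CPM in 28.02% of hair cell-like and 11.7% of supporting cell-like cells. Neuron markers had a median of -2.03 ± 0.656 (percentile 1.35, 4 members), with the neurofilament gene NEFL at 13.9 ± 14.7 against 130 ± 124.6 CPM. Stromal and melanocyte markers had 1 measured member each and endothelial, immune and dark cell markers 2 each, too few for a median. Scaling moved the median of all genes by 0.23 with median-of-ratios factors and by 0.32 with mean log2 values, and the list medians are relative to it. Setting genes with 0 counts in a class to 3 counts moved no list median of this comparison by more than 0.066.

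Hair cell-like cells were divided further to ask whether type I and type II hair cells, which differ in their nerve terminals, could be separated. Type I-like cells (sub-cluster 3) were 40 in number, 22.0% (16.2 to 28.7%) of hair cell-like cells. Type II-like cells (sub-cluster 1) made up 85, 46.7% (39.3 to 54.2%), including all 13 cells of the developing cluster. An unnamed sub-cluster 2 held 57 cells, 31.3% (24.7 to 38.6%), with a median of 2062 genes per cell. The type I-like name rests on 5 detected markers, whereas the type II-like sub-cluster had 3 detected markers of each type. Clustering on the other gene set gave a type I-like share of 12.1%, and leaving out plates gave 12.5 to 22.5%, with 13.4% without plate 2, 13.8% without plate 3 and 12.5% without plate 6.

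In type I-like against the other hair cell-like cells, the potassium channel subunit gene KCNAB1 had 2264 ± 961 against 156.6 ± 122.7 CPM and OCM 27126 ± 4420 against 4756 ± 1800 CPM, both markers behind the name. Their log2 ratios of 3.85 and 2.51 were 6.63 and 5.70 as differences of mean log2(CPM + 1). Outside the markers, the opioid precursor gene PENK had 533 ± 743 against 6.87 ± 10.8 CPM, reaching 10 CPM in 32.5% of type I-like cells. CYP26A1, which encodes an enzyme that degrades retinoic acid, had 213.8 ± 47.1 against 14.96 ± 16.5 CPM. CPZ, a carboxypeptidase gene, had 974 ± 140 against 83.8 ± 46.6 CPM, and TPD52L1 (log2 ratio 4.00) and SPATS2L (3.19) were also higher. The guidance gene SEMA6D (122.1 ± 41.5 CPM in the other cells), the Wnt activator gene RSPO3 (59.2 ± 15.3 CPM) and KAZALD1 (57.8 ± 14.2 CPM) had 0 counts in the 40 type I-like cells, which allows up to 7.5% of cells. The collagen gene COL5A1 (log2 ratio -6.71), SS2 (-5.38) and SKOR2 (-5.14) were lower.

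Striolar markers had a higher median in type I-like cells (2.31 ± 2.72, percentile 100), but their plate medians ran from -2.21 to 4.40. Of the 5 members, 2 were higher on every plate. The transcription factor gene ISL1 had 275.8 ± 110 against 48.99 ± 49.01 CPM. OCM and ADAM11, 2 of the 5 members, are also type I markers behind the name. Developing hair cell markers were lower (median -2.30 ± 1.07, percentile 0.07), with the transcription factor gene ATOH1 at 0.189 ± 0.422 against 25.6 ± 12.4 CPM and DLL1 at 2.95 ± 4.21 against 58.3 ± 37.0 CPM. Supporting cell markers were also lower (median -2.32 ± 1.14, percentile 0), as were the gap junction and ion transport list (-1.62 ± 0.756, percentile 0.02, or -1.39 with genes at 0 set to 3 counts), glial markers (-2.99 ± 1.60, percentile 0.16) and the matrix list (-0.68 ± 0.601, percentile 0.73, or -0.51 in the same way). Within these lists FXYD6 had 0 counts against 62.9 ± 41.3 CPM and the otogelin gene OTOG 149.3 ± 96.2 against 940 ± 573 CPM, while TNC (180 ± 109.1 against 41.3 ± 30.7 CPM) was higher.

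In the type II-like sub-cluster the proton channel gene HVCN1 had 384 ± 118.5 against 11.6 ± 20.8 CPM in the other hair cell-like cells, the transcription factor gene NHLH1 135.9 ± 47.9 against 4.19 ± 4.16 CPM, and STMN1, which encodes the microtubule regulator stathmin, 549 ± 276.1 against 55.7 ± 17.1 CPM. GNG13 (log2 ratio 3.72), CISH (4.26) and KAZALD1 (3.27) were also higher. Potassium channel genes KCNQ5 (5.49 ± 11.8 against 594 ± 137.5 CPM) and KCNAB1 (83.98 ± 145.1 against 1222 ± 619 CPM) were lower, together with ETNPPL (-6.54), DSCC1 (-3.78), LTK (-3.38) and TNNC2 (-3.37). Developing hair cell markers were higher (median 1.51 ± 0.698, percentile 99.8), with ATOH1 at 34.5 ± 9.89 against 7.88 ± 13.1 CPM and in 51.8% against 7.22% of cells. The Notch list (0.71 ± 0.672, percentile 99.9), stress list (0.75 ± 0.238, percentile 99.96), apoptosis list (0.63 ± 0.208, percentile 99.4) and supporting cell markers (1.18 ± 1.63, percentile 100) were higher. The plate medians of the apoptosis list all lay below its median, from -0.058 to 0.46. Type I markers (-2.62 ± 0.538, percentile 0) and striolar markers (-2.28 ± 0.813, percentile 0.01) were lower, and oxidative phosphorylation genes slightly so (-0.20 ± 0.305, percentile 0.03). The type II markers that gave the name were not higher as a list (median -0.24 ± 0.577, percentile 17.8, 3 of 6 members higher). The gap junction list had a median of -0.66 ± 0.557 (percentile 0.1), but 0.63 without plate 2 and 0.18 as the difference of mean log2(CPM + 1). Its plate medians all lay above -0.66, from -0.63 to 0.56. When 4 sub-clusters were made, 31 developing hair cell-like cells formed their own and HVCN1 (-2.74), NHLH1 (-1.58), GNG13 (-1.74), STMN1 (-0.54), ATOH1 (-0.65) and the Notch (-0.15) and stress (-0.03) lists turned direction in the remaining 54 type II-like cells.

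The 13 cells of the developing cluster were set against the other hair cell-like cells, with no SD over plates because no plate held 5 of them. HVCN1 had 1869 against 59.7 CPM, the phosphatase gene DUSP4 326 against 7.21 CPM and the serotonin receptor gene HTR3A 175.6 against 3.76 CPM. PKN3 (log2 ratio 6.40), CA8 (5.98) and C14orf132 (5.03) were also higher. KCNAB1 (694 CPM in the other cells), NMB (418 CPM), CPZ (304 CPM) and ANO2 (297.2 CPM) had 0 counts in the 13 cells, which allows up to 23.1% of cells, and ATP8B1 (-8.94) and PTN (-7.81) were lower. The naming markers had a median of 1.86 (percentile 99.95), with ATOH1 at 94.2 against 14.8 CPM, DLL1 at 148.8 against 38.8 CPM and HES6 at 132.7 against 5.59 CPM. Of 71 ribosomal protein genes 63 were higher (median 0.49, percentile 100), such as RPLP0 at 1266 against 508 CPM. Ribbon synapse genes (median -1.90, percentile 0), retinoic acid genes (-2.19, percentile 0.13, or -1.68 with genes at 0 set to 3 counts), gap junction genes (-1.63, percentile 0.07) and type I markers (-2.87, percentile 0.01, or -2.59 in the same way) were lower, with FXYD6 (467 against 18.7 CPM) the exception in the gap junction list. Cell cycle genes had a median of 0.98 (percentile 99.6) but a mean of -0.079, with the cyclin gene CCNB2 (53.9 against 10.4 CPM) higher and the replication genes MCM4 (-3.72) and MCM2 (0 counts against 10.9 CPM) lower.

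Sub-cluster 2, the hair cell-like cells with few detected genes, had higher levels of RBBP6 (223.5 ± 110 against 37.3 ± 17.4 CPM), the transcription activator gene CAMTA1 (log2 ratio 2.01) and RSPO3 (103.6 ± 27.8 against 21.4 ± 8.44 CPM). POLK, a DNA polymerase gene (log2 ratio 2.27), the amylase gene AMY2A (2.16) and the ubiquitin ligase gene NEDD4L (1.89) were also higher. RBBP6 (47.4% against 54.4%), CAMTA1 (36.8% against 40%) and AMY2A (47.4% against 53.6%) reached 10 CPM in shares of both sides with overlapping intervals, so their higher means did not come with a larger share of cells. ASS1 of the urea cycle (14.2 ± 22.5 against 283.2 ± 124.5 CPM), ARMC2 (-4.36), ACADSB (-4.22), CISH (-3.52), BTBD10 (-3.52) and C15orf61 (-3.19) were lower. Ribbon synapse genes had a median of 0.46 ± 0.503 (percentile 99.1) and oxidative phosphorylation genes 0.15 ± 0.306 (percentile 99.4). Supporting cell markers (-0.89 ± 1.93, percentile 0.03) and the stress list (-0.62 ± 0.289, percentile 0.98) were lower, the latter with GADD45B at 0 counts, ATF3 at 28.01 ± 37.5 against 254.8 ± 77.7 CPM and DUSP1 at a log2 ratio of -2.99. The hair bundle median was 0.44 ± 0.240 (percentile 99.6), with PTPRQ at 2001 ± 906 against 604 ± 81.9 CPM, but it was -0.63 as the difference of mean log2(CPM + 1).

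Supporting cell-like cells fell into 3 sub-clusters of 54, 31 and 9 cells, 57.4% (46.8 to 67.6%), 32.98% (23.6 to 43.4%) and 9.57% (4.47 to 17.4%), none of which had enough detected markers for a name. For the larger pair, 3 plates held 5 cells of both sides. Sub-cluster 1, with a median of 1426 genes per cell, had higher levels of the collagen gene COL8A2 (893 ± 170 against 173.4 ± 40.3 CPM, SD of 3 plates), the matrix proteoglycan gene VCAN (257.9 ± 36.3 against 48.5 ± 58.6 CPM) and the cadherin-family gene FAT1 (536 ± 176.6 against 52.7 ± 47.8 CPM). ANKRD17 (log2 ratio 2.64), ADAM9 (2.61) and PRRC2B (2.41) were also higher on these plates, although ADAM9 and PRRC2B did not reach 10 CPM in a larger share of cells (31.5% against 37.5% and 48.1% against 52.5%). From the summed counts of the cells of all plates the log2 ratios were 0.59 for ADAM9, 1.75 for COL8A2, 1.92 for ANKRD17, 2.09 for PRRC2B, 2.13 for FAT1 and 2.60 for VCAN. The matrix list had a median of 0.80 ± 0.232 (percentile 99.9), with the otolin gene OTOL1 at 1899 ± 413 against 458 ± 157.7 CPM, and striolar markers a median of -2.19 ± 3.07 (percentile 0.5). TBC1D7 and TCEA1 had 0 counts in these 54 cells, which allows up to 5.56% of cells, against 86.5 ± 28.5 and 66.4 ± 63.9 CPM. The proteasome gene PSMC6 (-7.28), GMPPA (-6.65), PCSK5 (-6.54) and ACKR3 (-5.17) were lower, with -2.32 for PCSK5, -4.60 for PSMC6, -6.26 for ACKR3 and -6.91 for GMPPA from the summed counts of all plates.

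In sub-cluster 2 of the supporting cell-like cells, striolar markers had a higher median than in the rest (4.08 ± 4.82, percentile 100, 3 plates). Their plate medians ran from 0 to 8.80. Extrastriolar markers also had a higher median (1.34 ± 2.06, percentile 91.8, 3 members). With 4 sub-clusters, 3 of the 31 cells formed a sub-cluster named striolar-like. The striolar values are thus not shown to hold for the whole sub-cluster. ISL1 had 591 ± 232.5 against 34.1 ± 58.5 CPM and the transcription factor gene GATA3 161.99 ± 244.2 against 7.35 ± 6.56 CPM, while OCM (-1.08) was lower. NEFL (170 ± 124.96 against 3.12 ± 5.41 CPM), GMPPA (5.16), FSCN1 (4.07), ARMC7 (3.81) and the sulfotransferase gene CHST8 (3.63) were also higher on these plates. From the summed counts of the cells of all plates the log2 ratios were only 0.40 for CHST8, 0.41 for FSCN1, 1.44 for NEFL and 1.53 for ARMC7, but 2.74 for ISL1, 4.03 for GATA3 and 5.64 for GMPPA. VCAN (-4.71), CALB2 (-4.03), the splicing factor gene PRPF8 (-3.53), ANKRD17 (-3.44), ARID1B (-3.03) and IFRD1 (-2.75) were lower. Summed counts gave -2.15 for VCAN, -1.94 for CALB2, -2.54 for PRPF8, -1.70 for ANKRD17, -3.57 for ARID1B and -2.12 for IFRD1. Matrix genes had a median of -1.05 ± 0.361 (percentile 0.06), which was 0.16 as the difference of mean log2(CPM + 1), ribbon synapse genes -0.79 ± 1.37 (percentile 0.75) and glial markers -3.59 ± 3.76 (percentile 0.2). Plate medians ran from -1.02 to -0.33 for matrix genes, -2.38 to 0 for ribbon synapse genes and -5.25 to 1.88 for glial markers. The glial direction thus differed between plates, and the rest includes sub-cluster 3, in which glial markers were higher. With 2 sub-clusters FSCN1 (-1.60) and CHST8 (-1.11) turned direction.

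The 9 cells of sub-cluster 3 came from plates 2, 3 and 4, with 5, 1 and 3 cells, and have no SD over plates. OC90 had 3905 against 0.512 CPM and was found in 44.4% of them, LRRN4 had 3193 against 4.71 CPM and CTGF, a matricellular growth factor gene, 685 against 0.857 CPM. SLC5A11 (355 CPM against 0 counts in 85 cells, which allows up to 3.53%), PHLDA2 (log2 ratio 7.31) and SLC25A25 (6.43) were also higher. Without plate 2, which held 5 of the 9 cells, OC90 had a log2 ratio of -0.67 and FOSL2 of -0.95. The stress list was higher (median 1.09, percentile 99.9), with GADD45B at 1929 against 60.5 CPM, MYC at 256.5 against 10.8 CPM and DDIT3 at 212.3 against 15.5 CPM. Glial markers were higher too (5.38, percentile 99.98), but their median was 0.59 without plate 2 and -0.66 in the sub-cluster matched with set B genes. Hair cell markers (2.09), ribbon synapse genes (1.03) and mechanotransduction genes (0.94) were higher only through 1 cell with 5482 genes and a marker score of 0.902, above the upper bound used below. Without this cell their medians were -1.74, -0.84 and -0.64. Ribosomal protein genes (-0.75, percentile 0.05), supporting cell markers (-1.19, percentile 0.68) and striolar markers (-5.56, percentile 0.01, or -4.88 with genes at 0 set to 3 counts) were lower. The guidance receptor gene ROBO2 (-6.03), STON2 (-5.36), ZNF423 (-5.13), MCOLN3 (-5.04), the tectorin gene TECTA (-4.80) and TBCA (-4.28) were lower as well.

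A score of hair cell minus supporting cell markers was used to look for cells between the classes, since supporting cells of birds can give rise to hair cells. Between the bounds of 0.25 and 0.75 lay 15 of the cells kept, 5.43% (3.07 to 8.81%), of which 11 were hair cell-like and 4 supporting cell-like. This is a range of a score and not a cell type, and 12 cells lay within 0.1 of the lower and 17 within 0.1 of the upper bound. ATOH1 reached 10 CPM in 3 of the 15 cells (20.0%, 4.33 to 48.1%), in 11 of 89 cells below (12.4%, 6.33 to 21.04%) and in 48 of the cells above (27.9%, 21.4 to 35.2%), with a median of 0 CPM in each range. JAG1 was found in 20.0% of the 15 cells, 87.6% of those below, with a median of 642 CPM, and 6.98% of those above. The Notch ligand gene DLL1 was found in 33.3% (11.8 to 61.6%), 4.49% and 20.9%, and PCNA, a replication factor gene, in 33.3% (11.8 to 61.6%), 22.5% and 47.7%. The intervals of the 15 cells overlap those of at least 1 neighbouring range for each of these genes. Their median number of genes was 1664, against 1803 below and 3469 above, and bounds of 0.33 and 0.67 held 2.54% of cells.

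Plates 2 to 6 had median totals of 396421, 332013, 406617, 338396 and 442238 counts and medians of 3173, 2754, 2479, 2754 and 2131.5 genes per cell. The filter removed 4, 3, 5, 5 and 7 cells from them. Hair cell-like cells made up 67.3% (52.5 to 80.1%), 76% (61.8 to 86.9%), 52.5% (39.3 to 65.4%), 65.1% (52.03 to 76.7%) and 71.7% (57.7 to 83.2%). HINTW, a gene of the female-specific W chromosome of birds that was chosen after its values were seen, reached 10 CPM in all 49 and 50 cells of plates 2 and 3. On plates 4, 5 and 6 it did so in 49.2% (36.1 to 62.3%), 55.6% (42.5 to 68.1%) and 60.4% (46.004 to 73.5%) of cells.

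**Figure D3:**
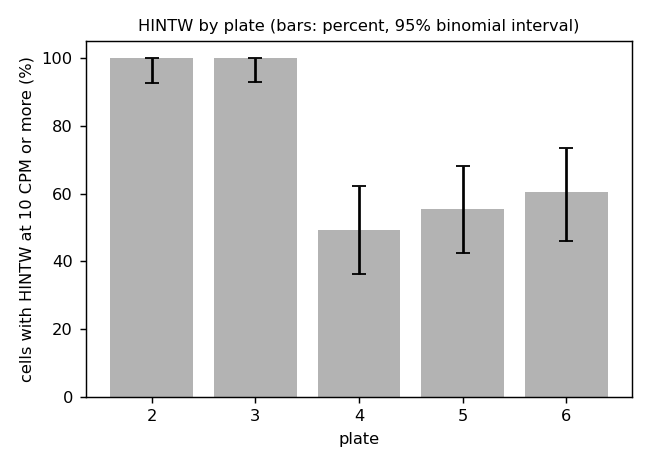
Percent of cells with HINTW at 10 CPM or more (vertical axis) on plates 2 to 6 (horizontal axis), with exact 95% binomial intervals as error bars. Plates 2 and 3 are at 100%, and plates 4, 5 and 6 are at 49.2, 55.6 and 60.4%.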

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

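Of the tests in this part, all tests of explanations were chosen after the result was seen. The plate comparison and the look at cells outside the main measurement were fixed rules.

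The median log2 ratio of the retinoic acid list was 2.27 on plate 3, far from the 0 to 0.097 of the other 4 plates. The list has 9 measured members, and plate 3 held 12 supporting cell-like cells. On plates 2 and 5 the median was 0, which can arise where the middle member has no counts in either class. The value on plate 3 stood out by its gap to the nearest plate, the only 1 of 22 measures over 5 plates to do so. Chance alone marks about 1 in 20 such groups.

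Signal appeared in cells outside the main measurement. Of the 24 cells below the filter, 17 had a larger share of the supporting cell than of the hair cell markers at 10 CPM or more, 70.8% (48.9 to 87.4%), and in 7 the hair cell share was larger. GJB6 was found in 18 of the 24, with a mean of 15946 CPM, and the synaptic gene OTOF in 6. Their median was 145378 counts and 818 genes.

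Each class held a sub-cluster of cells with few detected genes, at medians of 2062 genes in hair cell-like sub-cluster 2 and 1426 in supporting cell-like sub-cluster 1. Fewer counts do not account for it, because at 50000 counts per cell the few-gene sub-clusters still had at most 58% of the genes of hair cell-like sub-cluster 1 and supporting cell-like sub-cluster 2. A single plate is not the whole cause either, since such cells made up at least 15.2% of either class on every plate. Their share still differed between plates, from 15.2% on plate 2 to 46.9% on plate 4 in hair cell-like and from 18.8% on plate 2 to 80% on plate 6 in supporting cell-like cells, and why it did was not tested. Loss of cytoplasmic mRNA from damaged cells would put the ribosomal protein and oxidative phosphorylation lists among the lowest 2.5% of random lists. In hair cell-like cells their medians were 0.017 ± 0.311 (percentile 81.8) and 0.15 ± 0.306 (99.4). In supporting cell-like cells they were 0.15 ± 0.271 (95.5), which goes against damage, and -0.29 ± 0.222 (4.36), just above the lowest 2.5%. Damage cannot be told apart from other causes in either class, because the nearer list lay only 0.89 and 0.12 SD over plates above that lowest range. The design names no biological group for these cells, and no biological explanation was tested.

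The 15 cells between the marker score bounds included hair cell-like and supporting cell-like cells. Few detected markers may put a cell there, and 9 of the 15 had fewer genes than the median cell, too few cells to tell this from an even split (interval 32.3 to 83.7%). A second cell in the well could also do so, and 5 of the 15 had 3904 to 5043 genes. In those 5 cells the supporting cell markers stood at 18.6% and the hair cell markers at 84.5% of the level of their own class, GJB6 at 4443 against 23434 CPM and OTOF at 5147 against 4772 CPM, a level that a pair of cells with unequal RNA, or a cell of intermediate type, could both give. ATOH1 was found in 3 of these 5 cells and in 0 of the other 10, which allows up to 30.0%, and no biological explanation was tested.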

How the results depend on the processing

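Tests chosen after the data were seen are plates 4 to 6 or 2 and 3 alone, and the omission of small supporting cell-like clusters, of few-gene sub-clusters, of cells between the score bounds or of the supporting cell-like cell above them. Over 461 results, 6788 alternative values were computed, of which 6132 moved by less than their spread, 602 moved by more and 54 were counted as reversed. A change of sign was counted as reversed only where the main value was larger in size than its spread. Changes of sign in main values smaller than their spread are therefore not among the 54. Where no SD over plates existed, a fixed value stood for the spread. At most 4 cells changed class under any clustering setting, but the developing cluster held 0 to 32 cells, and 5 settings had a glial cell-like cluster of at most 4 cells. The cause of a difference was not tested. Depth limits genes near 0 CPM and groups of 9 and 13 cells.

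Under a stricter cell filter the hair cell-like share was 79.1% and the matrix list -4.38. The matrix list was -4.50 with no gene filter, -3.74 on plates 4 to 6, -3.86 without small clusters, -3.57 without few-gene sub-clusters and -5.46 to -4.62 with 1 plate left out. The gap junction list was 0.12 with clustering genes of both sets, 0.14 with 12 clusters, 0.15 without cells between the bounds and -4.11 to -1.67 with 1 plate left out. A pseudocount of 5 CPM, which lowers ratios by construction, gave 3.80 for mechanotransduction, 2.26 for hair bundle, 1.85 for ribbon synapse and -4.03 for matrix. Mean log2(CPM + 1) gave 3.11 for mechanotransduction, -1.23 for Notch, -1.27 for matrix and 0.0048 for ribosomal proteins. TECTB was 0.056 on plates 4 to 6, and EGR3 ran from -4.14 to 1.25 with 1 plate left out. Bounds of 0.33 and 0.67 held 2.54% of cells.

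The type I-like share was 12.1% with set B genes and 12.5 to 22.5% with 1 plate left out. In type I-like cells mean log2(CPM + 1) gave 6.63 for KCNAB1 and 5.70 for OCM. In type II-like cells it gave 0.26 for ATP5F1B and 0.18 for the gap junction list, which ran from -0.67 to 0.63 with 1 plate left out. With 2 sub-clusters type I-like and type II-like cells were compared as 1 group, with reversals of DSCC1 (0.73), ETNPPL (0.27), ISL1 (1.23), KCNAB1 (1.54), KCNQ5 (0.35), LTK (0.36), OCM (0.70), TNFRSF10B (2.47), TNNC2 (0.49) and the gap junction list (0.30). With 4 sub-clusters 31 developing hair cell-like cells were in the other group, with reversals of ATOH1 (-0.65), FOSL2 (-1.03), FXYD6 (-0.83), GNG13 (-1.74), HES6 (-1.08), HMOX1 (-0.28), HVCN1 (-2.74), NHLH1 (-1.58), STMN1 (-0.54), Notch (-0.15) and stress (-0.030). In hair cell-like sub-cluster 2, mean log2(CPM + 1) gave ATP5E -0.11, SOD1 -0.18, UQCRQ -0.039 and hair bundle -0.63.

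In supporting cell-like sub-cluster 2, mean log2(CPM + 1) gave OCM 0.024 and matrix 0.16, 2 sub-clusters gave CHST8 -1.11, COL4A1 1.81, FSCN1 -1.60 and OC90 1.49, 4 sub-clusters gave COL2A1 -1.41, set B genes gave COL4A1 2.40, and OC90 ran from -11.1 to 1.90 with 1 plate left out. COL2A1 in sub-cluster 1 was 0.035 with summed counts. In sub-cluster 3, FOSL2 ran from -0.95 to 2.94 and OC90 from -0.67 to 11.93 with 1 plate left out. Its hair cell markers (-1.74), ribbon synapse (-0.84) and mechanotransduction (-0.64) lists reversed without the cell above the score bounds, and also without plate 2, which held it, running from -1.62 to 3.28, -1.01 to 1.66 and -0.96 to 1.24 with 1 plate left out. Its glial markers were -0.66 with set B genes and 0.59 without plate 2. With 2 sub-clusters, type I-like cells and supporting cell-like sub-cluster 3 had no match and gave no value. Classes were averaged within each plate, and no paired test was made because no comparison of cell groups was tested.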

Other observations

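All genes, cell sets and tests in this part were chosen after values of the kind were seen, except that the tests of counting depth and of Z-linked genes for HINTW had their predictions written before their results.

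Cells of the type I-like sub-cluster differed among themselves, and their grouping depended on the gene set. When clustering was repeated with set B genes, 21 of the 40 type I-like cells were type I-like again and 19 were not. Of those 19, 18 fell in the sub-cluster then named type II-like and 1 in the unnamed one. Among type I markers, KCNAB1 reached 10 CPM in 20 of the 21 and 9 of the 19 cells. TNC did so in 18 and 11, and ADAM11 in 2 and 8. The mechanotransduction channel gene TMC2 reached 10 CPM in 2 of the 21 cells (mean 43.1 CPM) and in 17 of the 19 (1205 CPM). The calretinin gene CALB2 was found in 5 of 21 and 13 of 19 cells, ISL1 in 9 and 14, TECTB in 1 and 7, and GATA3 in 0 of 21, which allows up to 14.3%, and 7 of 19. The potassium channel gene KCNA10 showed the reverse, in 21 of 21 cells at 2085 CPM and in 8 of 19 at 934 CPM, and the neurotrophin gene BDNF had 3517 and 1686 CPM. OCM was alike, at 27391 and 26020 CPM, and the median cell had 3280 and 3613 genes. Both parts held cells of all 5 plates.

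Supporting cell-like cells with striolar markers were few. TECTB, which encodes a tectorin, was found in 12, GATA3 in 13 and ISL1 in 13 of 94 cells, and in its positive cells TECTB had a mean of 8042 CPM. ISL1 was found in 7 of the 13 cells with GATA3, 53.8% (25.1 to 80.8%), and in 6 of the 81 without it, 7.41% (2.77 to 15.4%). All 3 genes occurred together in 3 cells. At least 1 of 11 mitotic genes was found in 7 of 94 supporting cell-like cells, 7.45% (3.05 to 14.7%), and in 26 hair cell-like cells, 14.3% (9.55 to 20.2%). The median hair cell-like cell had more detected genes (3458 against 1823.5), so these shares cannot be compared directly between the classes. At least 3 were found in 2 of 94 supporting cell-like cells, 2.13% (0.26 to 7.47%), and in 0 hair cell-like cells, which allows up to 1.65%.

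HINTW was found in all 99 cells of plates 2 and 3 and in 97 cells of plates 4 to 6, 54.8% (47.2 to 62.3%). Counting depth does not account for the cells without it, whose median total was 105.9% of that of cells with it, and 79 of these 80 cells had exactly 0 counts. A mix of animals shared by all plates does not either, since the lower bound on plates 2 and 3 was 92.7%. The hypothesis that cells without HINTW came from male animals predicts higher Z-linked genes in them, and among hair cell-like cells of plates 4 to 6 the 77 measured Z-linked genes had a median log2 ratio of 0.37, a 1.29-fold difference at percentile 99.93 of random lists, with 3 of 3 plates positive. Other W-linked genes go the same way. ATP5A1W and HNRNPKL reached 10 CPM in 1 of these 80 cells each, against 37.1% and 29.9% of cells with HINTW on plates 4 to 6. SPIN1W, SMAD2W and UBE2R2L reached it in 0 of the 80, against only 15.5%, 15.5% and 13.4%. SMAD2W and UBE2R2L had 0 counts there, which allows up to 3.75%. Each of these genes had a larger share on plates 2 and 3, such as 60.6% for ATP5A1W and 34.3% for UBE2R2L. Why it did was not tested. The HINTW and Z-linked values go with plates 2 and 3 from female animals and plates 4 to 6 from both sexes. That hypothesis was found and tested on the same cells. On plates 4 to 6 the hair cell-like share was 62.9% in cells with and 62.5% in cells without HINTW.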
